A study of Mus musculus with 16 samples.

How the data were processed

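RNA sequencing of sorted retinal microglia was analysed from the deposited gene table, which holds 54532 genes for 8 OIR and 8 nonOIR libraries. Per the labels' protocols, libraries were made with a SMARTer v4 and Nextera XT workflow from 750 pg of total RNA with 12 cycles of cDNA amplification, 150 pg of cDNA was tagmented, and reads were single and 50 bases long. This workflow does not mark strand, so reads of genes that overlap on opposite strands cannot be told apart. Without molecular identifiers, amplified reads are not independent molecules, so intervals and floors cover counting error only.

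The deposited counts are whole reads per gene, per the file headers. The submitters' processing notes name FastQC 0.72, STAR 2.6.0b-1, featureCounts 1.6.2, DESeq2 2.11.40.2 (a wrapper's version number) and the mm10 build, without roles, and the annotation is not given in the sources used here. The normalized signal columns deposited by the authors equal the counts divided by 1 factor per library, and the authors' base mean is a signal averaged over libraries. The authors' deposited table also holds a log2 fold change with its standard error, a Wald score that is their ratio, and p-values with adjusted p-values. The counts were used for all tests, and the authors' other columns only to compare calls. No column of per-sample values was left unused. Of the gene identifiers 54409 were found in GENCODE M21, whose coordinates are on the same build, and 100 symbols were shared by more than 1 identifier. All 37 mitochondrial genes stood at 0 counts in every library, so a mitochondrial share could not be measured.

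Groups and replicate numbers came from the labels, and the lane from a code in the description label, which may also mark a batch of animals or of library preparation. Counts were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over 12496 genes and a threshold of 0.05. All edgeR adjusted p-values in the text come from this quasi-likelihood test. The biological coefficient of variation was 40.3%. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided), adjusted over 24 lists, and again with an estimated correlation and with fry. Of 585 list genes 584 were in the table. Scores of other cell types were means of log2(CPM + 1), with CPM taken after TMM scaling, and were compared, like library totals and components, by two-sided exact permutation tests, whose smallest p for 8 against 8 is 0.000155. Binomial intervals are exact (Clopper-Pearson, 95%).

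The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, among genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and at least 7 of its 8 libraries above the other group's median, the 12 largest rises and the 12 largest falls. It added up to 4 members with the lowest p from each microglial, process or secreted list, up to 3 members with the highest CPM from each list of another cell type, and the sort markers. Alternatives covered scaling, filters, lane, replicate number, covariates, a minimum fold of 1.5, DESeq2 1.42.0, limma-voom and the omission of each library.

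On simulated counts for the same design and 12496 genes, the test found 25 of 67 genes changed 1.5-fold (37.3%), 43 of 67 changed 2-fold (64.2%) and 59 of 66 changed 4-fold (89.4%), and 3 of 130 calls were false (2.31%). The simulation drew each gene independently, without lane structure, and planted changes only in genes above a minimum mean count. Its rates need not hold for the real libraries. No pair of libraries within a group matched within sampling noise (chi-square per gene of at least 16.0), so none was treated as a repeat deposit, although separately amplified libraries of 1 sample would also exceed that noise. Genes with near-identical copies or many processed pseudogenes (the globins, Ly6c1 and Ly6c2, Gapdh, Pgk1, Pgam1, Ftl1 and ribosomal protein genes) have uncertain counts, because such reads can be split or dropped in counting. Values of some single genes that the rule names are not reported here.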

Results

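RNA was measured in retinal microglia, the resident macrophages of the retina, sorted from mouse pups at postnatal day 17. The comparison set oxygen-induced retinopathy (OIR) against retinas without it (nonOIR). In OIR, newborn mice are kept in high oxygen and then returned to room air, after which the retina becomes hypoxic and grows abnormal vessel tufts. The cells came from Cx3cr1-CreERT2 mice carrying a tdTomato reporter, which was switched on by tamoxifen (5 µl at 21 mg per ml) at postnatal day 1. They were sorted as tdTomato-positive, CD11b-positive and low in CD45, without Ly6C or Ly6G on the surface, a gate meant to leave out monocytes and granulocytes. There were 8 OIR and 8 nonOIR libraries, each made from 750 pg of total RNA. In each group 5 libraries carried the first lane code and 3 the second, and the labels do not say whether this code is also a batch of animals or of library preparation. The labels do not say that the libraries come from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

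Gene counts summed to between 13.6 M and 30.0 M (mega-counts) per library. The mean total was 25.1 ± 3.24 M (SD, n = 8) in OIR and 22.3 ± 4.28 M (SD, n = 8) in nonOIR, a difference within the spread between libraries (two-sided exact permutation p = 0.163). The number of genes with a count was also similar, at 17822 ± 824 in OIR and 17774 ± 531 in nonOIR (SD, n = 8, exact permutation p = 0.899). The 20 highest genes took 20.7 ± 1.42% of counts in OIR and 22.98 ± 0.882% in nonOIR (SD, n = 8, exact permutation p = 0.00357, adjusted p = 0.0107 over the 3 measures). Of the genes that defined the sort, Cx3cr1 stood at 1760 ± 489 CPM (the count relative to the scaled library size) in OIR and 2262 ± 542 in nonOIR, Ptprc (CD45) at 465 ± 130 and 548 ± 105, and Itgam (CD11b) at 319 ± 94.5 and 303 ± 76.8 (SD, n = 8), and none of the 3 passed the test. With lane as a covariate Cx3cr1 passed as lower in OIR (log2 fold change -0.38, edgeR adjusted p = 0.000316), and it also did within each lane (edgeR adjusted p = 0.0322 and 0.0128). Ly6c1 had 3 counts over the OIR and 2 over the nonOIR libraries, and Ly6c2 and Ly6g had 0 in all 16, which allows up to 3 counts in each library, for counting error only. Ly6c1 and Ly6c2 are near-identical copies, so reads from either can be lost in counting.

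The first principal component of the 500 most variable genes held 29.7% of the variance and separated all 8 OIR from all 8 nonOIR libraries (exact permutation p = 0.000155, the smallest that 8 against 8 can give). OIR replicate 1 lay nearest to the nonOIR libraries on this component and far from every other library on the second, which held 11.1%. NonOIR replicate 8 stood apart on the third component, which held 8.72%. Components 2 and 4 differed between the lanes (exact permutation p = 0.0275 and 0.00375).

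**Figure D1:**
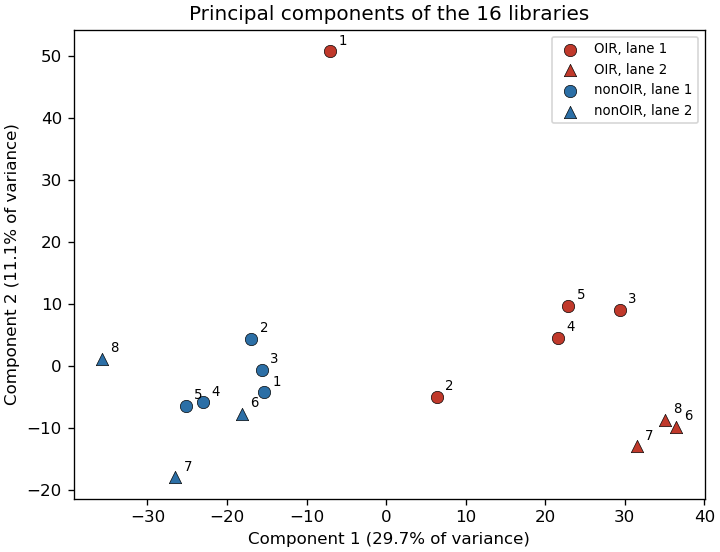
Each point is 1 of 16 libraries, placed by its scores on principal components 1 and 2 (29.7% and 11.1% of the variance of the 500 most variable genes), with colour for the group, shape for the lane and the replicate number beside it. The groups do not overlap on component 1, and OIR replicate 1 lies apart on component 2.

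Among changed genes that reached 10 CPM in the group where they were higher, the largest rises in OIR were in Mmp12, Hbb-bs, Lgals3, Ncapg and Hmox1. Mmp12, a macrophage elastase, rose 41.2-fold, from 1.39 ± 1.59 CPM in nonOIR to 56.6 ± 67.6 in OIR (SD, n = 8), with a log2 fold change of 5.36, or 6.00 without nonOIR replicate 7. Lgals3 (galectin-3) rose 20.9-fold, from 6.94 ± 2.96 to 145 ± 129 CPM. Hmox1, the inducible haem oxygenase, rose 16.9-fold, from 54.9 ± 19.96 to 929 ± 604 CPM. Among transcripts that fell, Hebp1, which encodes a haem-binding protein, fell to 0.312 of its nonOIR level, to 25.2 ± 3.68 CPM, and the microglial receptor gene P2ry12 from 11356 ± 1170 to 6613 ± 1531 CPM (SD, n = 8).

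Of 12496 genes tested, 1368 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 798 higher and 570 lower in OIR. The changes were larger upward: 319 genes were at least 2-fold higher and 67 at least 2-fold lower. In 253 genes the 8 OIR and the 8 nonOIR values did not overlap, where chance would give 1.94. Scaling by TMM (trimmed mean of M values) put 58.3% of the changed genes higher in OIR, scaling by library size alone put 73.7% higher, and upper-quartile scaling put 51.1% higher (675 higher and 647 lower).

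Named genes follow a rule fixed in advance, except Spp1, Gpnmb, Ccl6, Aldoc, Gapdh, Pgam1, Ccl9, C4b, Cfp, Treml4, Vim, Spc25, Ier3, Egr1 and Jun, which were chosen after their values were seen. The other genes above 10 CPM with the largest rises were Hbb-bs (adult beta globin, 23.8-fold, or 86.9-fold without nonOIR replicate 8), Adam8 (a cell-surface metalloprotease, 14.5-fold) and 7 genes of chromosome condensation and mitosis. The latter were Ncapg, Pimreg, Cdca3, Nek2, Prc1, Plk1 and Ccnb2, which rose between 11.7-fold (Ccnb2) and 17.6-fold (Ncapg). All 12 of these genes were above the nonOIR median in 8 of 8 OIR libraries, except Nek2, which was in 7. Mmp12, Ncapg and Nek2 passed in lane 2 and not in lane 1 (lane 1 edgeR adjusted p = 0.127, 0.0778 and 0.212). The log2 fold change of Ncapg was 2.90 in lane 1 and 8.77 in lane 2, where its nonOIR mean was 0.0420 CPM. The falls were smaller. Gpr165, an orphan receptor gene, fell to 0.320 of its nonOIR level, Upk1b to 0.381, the neuronal vesicle gene Snap25 to 0.404 and Sqle, an enzyme of cholesterol synthesis, to 0.456. The other 7 with the largest falls were 9430060I03Rik, Klf12, Klhdc8b, Calcrl, Nr6a1os, Adamts16 and the nuclear noncoding RNA Malat1, which fell to between 0.425 (9430060I03Rik) and 0.499 (Malat1). The call was lost when any of 10 single libraries was left out for 9430060I03Rik, which did not pass in lane 1 (log2 fold change -0.56, edgeR adjusted p = 0.244), any of 3 for Klf12 and for Calcrl, and nonOIR replicate 7 for Gpr165. Snap25 (edgeR adjusted p = 0.0388) lost its call when any of 11 single libraries was left out and did not pass within either lane, at a log2 fold change of -1.83 in lane 1 and -0.33 in lane 2. Klf12 (edgeR adjusted p = 0.122 and 0.177) and Calcrl (0.184 and 0.0579) did not pass within either lane. Gpr165 (edgeR adjusted p = 0.366), Upk1b (0.0686) and Nr6a1os (0.412) did not pass in lane 1, nor Adamts16 in lane 2 (0.0776).

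On the mouse genome build mm10, with positions from the GENCODE M21 annotation, Mmp12 (ENSMUSG00000049723) spans 7344381 to 7369499 on chromosome 9, with a log2 fold change of 5.36 ± 1.05 (SE, edgeR adjusted p = 0.00292). Lgals3 (ENSMUSG00000050335) lies on chromosome 14 from 47367751 to 47386160, with 4.38 ± 0.52 (SE, edgeR adjusted p = 0.000107). Hmox1 (ENSMUSG00000005413) lies on chromosome 8 from 75093621 to 75100589, with 4.08 ± 0.44 (SE, edgeR adjusted p = 2.98e-05). Hebp1 (ENSMUSG00000042770) lies on chromosome 6 from 135137522 to 135198022, with -1.68 ± 0.25 (SE, edgeR adjusted p = 0.000435), and P2ry12 (ENSMUSG00000036353) on chromosome 3 from 59216272 to 59262871, with -0.78 ± 0.12 (SE, edgeR adjusted p = 0.000617). Counts are per gene. Exons of Mmp12 overlap those of Mmp1b, those of Hebp1 overlap Fam234b and those of P2ry12 overlap Med12l, and the library kit does not mark strand, so reads of overlapping genes cannot be told apart by direction.

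**Figure D2:**
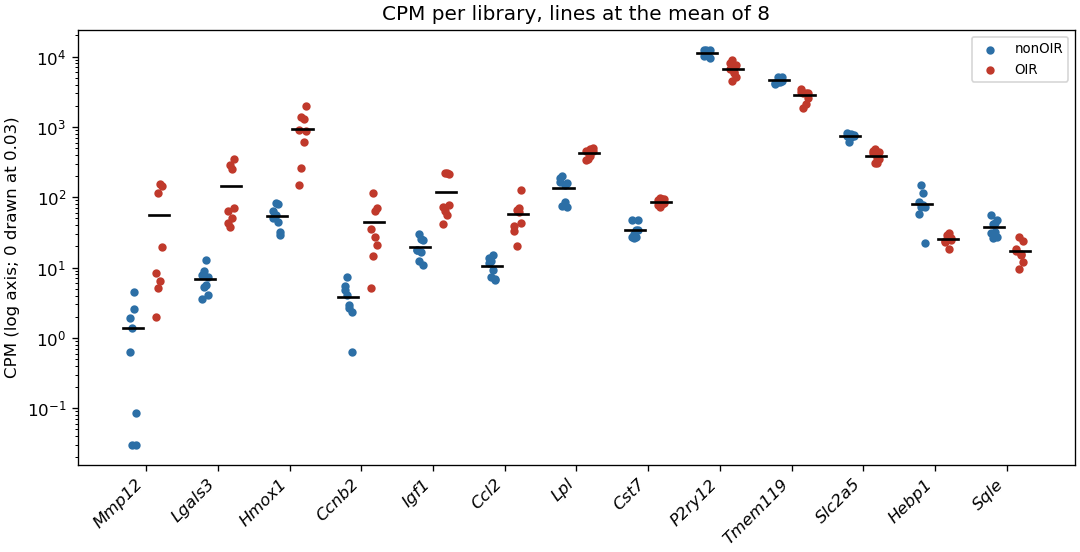
CPM on a log axis for 13 genes, 1 point per library (8 nonOIR in blue, 8 OIR in red), with a line at each group's mean and values of 0 drawn at the foot of the axis. Mmp12 spans 1.99 to 152 CPM over the OIR libraries, and Cst7, which rose 2.54-fold, is higher in all 8 OIR libraries than in any nonOIR library.

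Genes of the resting microglial state fell in OIR. Of 25 tested members of the homeostatic list, 11 fell and 0 rose (16 fell and 1 rose when adjusted over the list alone). The fructose transporter gene Slc2a5 fell from 744 ± 62.4 to 391 ± 67.5 CPM, Cst3 (cystatin C) from 32502 ± 3151 to 17204 ± 4244, and Tmem119 from 4570 ± 373 to 2797 ± 548 (SD, n = 8). For each of these, 8 of 8 nonOIR libraries lay above the OIR median. The list as a whole was shifted down by camera (adjusted p = 1.69e-08). This call was lost with an estimated correlation (camera adjusted p = 0.126) and kept with fry (fry adjusted p = 0.000962). It was also lost with the proliferation score as a covariate (camera adjusted p = 0.384, mean log2 fold change 0.11). That score does not overlap between the groups (r = 0.873 with group), so this fit cannot separate it from the group.

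Genes of the disease-associated microglial state, described in degenerating brain, rose in OIR. Of 26 tested members 13 rose and 1 fell, or 16 and 1 when adjusted over the list alone. Besides Lgals3, the cystatin gene Cst7 rose from 34.1 ± 8.49 to 86.7 ± 9.68 CPM, lipoprotein lipase (Lpl) from 137 ± 51.5 to 425 ± 61.1 and the receptor kinase gene Axl from 355 ± 70.7 to 731 ± 141 (SD, n = 8). Spp1 (osteopontin) rose 6.68-fold, to 268 ± 307 CPM, and Gpnmb 6.56-fold, to 30.3 ± 16.2 CPM (SD, n = 8), and the chemokine gene Ccl6 fell to 0.708 of its nonOIR level. The upward shift held by camera (adjusted p = 5.77e-10) and at adjusted p = 0.0199 with an estimated correlation. In the same libraries the monocyte list, given with the other cell types, was also shifted up, at adjusted p = 0.0244 with an estimated correlation.

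Cell division genes formed the most uniform group, with 28 of 30 tested members higher in OIR and 0 lower (30 and 0 adjusted over the list alone). Rrm2, a subunit of ribonucleotide reductase, rose from 5.88 ± 0.933 to 44.7 ± 23.8 CPM, and the cyclin gene Ccnb1 from 1.17 ± 0.356 to 11.8 ± 7.17 (SD, n = 8). The spindle genes Nusap1 and Bub1b rose 8.51-fold and 8.31-fold. The camera adjusted p was 3.25e-28, and 0.0254 with an estimated correlation. OIR replicate 1 had the lowest CPM among OIR libraries for Pimreg (1.07) and Nek2 (0.0397).

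Genes of energy metabolism were higher in OIR. In the glycolysis list 11 of 18 tested members rose and 1 fell (the same numbers adjusted over the list alone), among them Tpi1 from 134 ± 24.9 to 264 ± 51.1 CPM and Pkm from 223 ± 30.8 to 484 ± 151 (SD, n = 8), with Gpi1 up 1.71-fold and Aldoa up 1.81-fold. The member that fell was Aldoc, an aldolase of neural tissue. Of 21 tested genes of the response to hypoxia, 7 rose and 0 fell (9 and 0 adjusted over the list alone), including Ldha (1.74-fold), Plin2 (1.70-fold), Pgk1 (2.25-fold) and Bnip3 (1.83-fold). Of 29 tested nuclear genes of oxidative phosphorylation, 15 rose by 1.19-fold to 1.56-fold and 0 fell (20 and 0 adjusted over the list alone), led by Cox5b, Uqcrq, Uqcr11 and Cox7a2. These lists were shifted up by camera with adjusted p = 3.46e-06 for glycolysis, 3.52e-05 for hypoxia and 2.17e-09 for oxidative phosphorylation. All 3 calls were lost with an estimated correlation, at adjusted p = 0.146, 0.0942 and 0.215. Fry kept them (fry adjusted p = 0.00141, 0.00106 and 0.00959). The 3 camera calls were also lost with the proliferation score as a covariate, and the mean log2 fold changes turned to -0.59, -0.18 and -0.0600. Because that score separates the groups completely (r = 0.873 with group), this fit cannot tell its part from that of the group. Gapdh, Pgk1 and Pgam1 have many processed pseudogenes, and their low counts (21.2, 5.39 and 2.71 CPM in nonOIR) are uncertain for that reason.

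Genes of cholesterol synthesis fell, and genes of lipid efflux, transport and storage rose. Of 21 tested genes of cholesterol synthesis and its control, 7 fell and 0 rose (12 and 0 adjusted over the list alone), including Msmo1 from 189 ± 44.3 to 111 ± 10.5 CPM, Cyp51 from 89.7 ± 15.2 to 53.3 ± 9.71 and Sc5d from 60.9 ± 11.3 to 36.9 ± 5.36 (SD, n = 8), besides Sqle. Of 16 tested genes of lipid efflux, transport and storage, 7 rose and 0 fell (9 and 0 adjusted over the list alone), including Apoc1 from 12.6 ± 2.94 to 43.1 ± 9.09 CPM, the fatty acid binding protein gene Fabp5 (5.37-fold) and the sterol exporter gene Abcg1 (2.37-fold). Camera called the synthesis list down (adjusted p = 3.21e-06, and 0.0199 with an estimated correlation) and the efflux list up (adjusted p = 1.98e-07, and 0.0244 with an estimated correlation). The efflux list shares Lpl, Fabp5 and Apoe with the disease-associated list.

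Interferon-induced and inflammatory genes rose. In the interferon list 15 of 24 tested members rose and 0 fell (19 and 0 adjusted over the list alone), with Ifi27l2a from 31.9 ± 13.3 to 180 ± 88.0 CPM, Isg15 from 8.06 ± 3.36 to 25.3 ± 9.75 and Ifit3 and Usp18 up 2.605-fold and 2.16-fold. This list was shifted up by camera (adjusted p = 1.51e-14, and 0.0410 with an estimated correlation). Of 18 tested cytokine and chemokine genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone). Ccl2, a monocyte attractant, rose from 10.4 ± 3.31 to 57.8 ± 33.1 CPM, Ccl12 from 229 ± 43.5 to 432 ± 56.8 and Tnf from 2.35 ± 1.25 to 7.12 ± 2.08 (SD, n = 8), Ccl4 rose 3.33-fold, and the member that fell was Ccl9. That shift (camera adjusted p = 0.000532) was lost at adjusted p = 0.0565 with an estimated correlation and in lane 2 alone (adjusted p = 0.0863). Fry kept it over all libraries (fry adjusted p = 0.000186).

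The complement and antigen presentation lists were mixed. In the complement list 5 of 16 tested members rose and 1 fell (6 and 1 adjusted over the list alone). The anaphylatoxin receptor genes C3ar1 and C5ar1 rose 1.46-fold and 1.32-fold, Cfb (factor B) rose from 0.599 ± 0.281 to 3.02 ± 3.00 CPM (log2 fold change 2.32, or 1.73 without OIR replicate 3, which held 10.2 CPM), C4b and Cfp (properdin) rose 2.83-fold and 4.74-fold, and C5ar2 fell to 0.702 of its nonOIR level. The camera adjusted p of 0.0419 was lost at adjusted p = 0.387 with an estimated correlation. It was also lost when any of OIR replicates 1, 2, 4 and 5 or nonOIR replicates 6, 7 and 8 was left out, with adjusted p between 0.0588 and 0.133. Of 18 tested genes of antigen presentation, 2 rose (H2-K1 1.29-fold and Cd74 1.53-fold) and 2 fell (Cd80 to 0.573 and H2-DMa to 0.763), or 4 and 3 adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.577).

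Matrix and remodelling genes rose in OIR, with 6 of 15 tested members higher and 0 lower (6 and 0 adjusted over the list alone). Fibronectin (Fn1) rose from 3.21 ± 3.10 to 22.1 ± 12.9 CPM, the urokinase receptor gene Plaur from 15.9 ± 3.58 to 30.8 ± 8.99 and Tgfbi from 43.1 ± 7.65 to 65.5 ± 9.18 (SD, n = 8), besides Mmp12, Adam8 and Spp1. Fn1, Plaur and Tgfbi passed in lane 2 and not in lane 1 (lane 1 edgeR adjusted p = 0.0686, 0.0866 and 0.0752). The list was shifted up by camera (adjusted p = 0.000273, and 0.0343 with an estimated correlation). Among 15 tested secreted angiogenic factors 1 rose and 1 fell (2 and 2 adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.855). The growth factor gene Igf1 rose from 19.6 ± 6.81 to 121 ± 81.7 CPM and Ang (angiogenin) fell from 165 ± 25.7 to 116 ± 25.3. Hbegf, at 1.18 ± 0.612 CPM in nonOIR and 0.287 ± 0.324 in OIR, and Vegfb, at 21.9 ± 2.13 and 27.3 ± 3.97 (SD, n = 8), did not pass, though both did with lane as a covariate (log2 fold change -2.11 and 0.31, edgeR adjusted p = 0.0315 and 0.0405) and with DESeq2. Hbegf also passed when OIR replicate 5 was left out (log2 fold change -2.64, edgeR adjusted p = 0.0169).

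Lysosomal and stress genes changed in both directions, and camera called none of their lists shifted. Of 28 tested genes of lysosome and phagocytosis, 7 rose and 3 fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.137), with the galactosidase gene Gla up 3.48-fold and Ctsb (cathepsin B) up 1.45-fold. This list was called up with no low-count filter (adjusted p = 0.0248) and with the erythrocyte or proliferation score as a covariate (adjusted p = 0.0441 and 0.0348), and its score was 9.27 ± 0.0626 in OIR and 9.04 ± 0.102 in nonOIR (SD, n = 8, exact permutation p = 0.000311, unadjusted). Of 19 tested genes of the unfolded protein response, Atf3 rose 2.21-fold and Herpud1, Xbp1 and Dnajb9 fell to 0.723, 0.740 and 0.720 (1 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.855, direction down, with a median log2 fold change of 0.0205 and a mean of 0.13). Of 22 tested immediate early genes, which cell dissociation can induce, 4 rose and 2 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.786), with Ier3 and Egr1 up 2.53-fold and 2.54-fold and Jun down to 0.738. Their median log2 fold change was -0.14 and their mean 0.16, and their score was 4.44 ± 0.152 in OIR and 4.25 ± 0.0981 in nonOIR (SD, n = 8, exact permutation p = 0.0118, unadjusted), so the direction depends on the measure. None of 30 ribosomal protein genes changed, and 0 passed adjusted over the list alone. The median log2 fold change of the ribosomal genes, 0.19, was called up by camera (adjusted p = 0.00174) but not with an estimated correlation (adjusted p = 0.559).

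**Figure D3:**
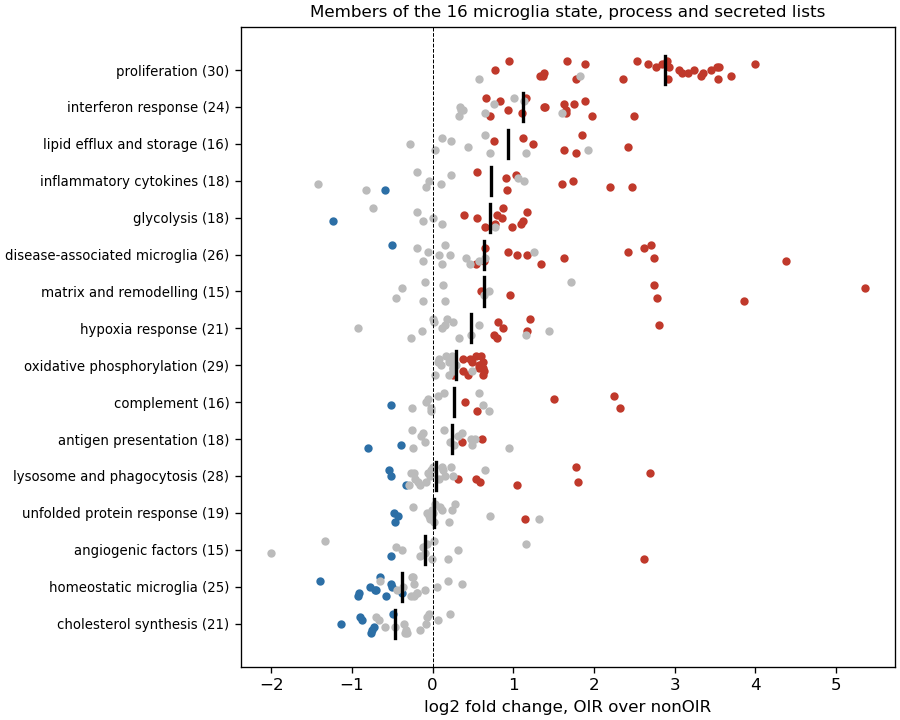
Log2 fold change (OIR over nonOIR) of each tested member of the 16 microglia state, process and secreted lists, with the number tested in brackets, 1 point per gene, red where it rose, blue where it fell and grey where it did not pass, and a black bar at the list median. Proliferation has the highest median (2.88) and cholesterol synthesis the lowest (-0.47).

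Transcripts of other cell types were measured in the same libraries to set their level beside the microglial changes. Of 3 tested erythrocyte genes, 2 globin genes rose and 0 fell (2 and 0 adjusted over the list alone): Hbb-bs stood at 80.1 ± 64.6 CPM against 3.31 ± 6.94 and Hbb-bt at 12.8 ± 11.5 against 1.38 ± 2.80, while Bpgm, at 14.0 ± 2.83 against 11.2 ± 3.90, did not pass (SD, n = 8, edgeR adjusted p = 0.376). The mean log2(CPM + 1) of the erythrocyte list was 2.36 ± 0.947 against 0.634 ± 0.327 (exact permutation p = 0.000466, adjusted p = 0.00256 over 11 lists). The nonOIR mean of Hbb-bs is carried by replicate 8 (20.3 CPM) and is 0.882 ± 1.01 CPM without it (SD, n = 7, edgeR adjusted p = 0.000616). Hbb-bt (edgeR adjusted p = 0.0426) lost its call when any of 13 other libraries was left out. Hbb-bs and Hbb-bt are near-identical copies and their split is uncertain. The monocyte list also scored higher, at 1.14 ± 0.142 against 0.707 ± 0.0626 (exact permutation p = 0.000155, the smallest possible, adjusted p = 0.00171). Of its 7 tested members Fn1, Treml4 and Ms4a4c rose (4 rose adjusted over the list alone), with the call of Ms4a4c lost when any of 9 single libraries was left out, while Ccr2, a receptor of recruited monocytes, stood at 5.22 ± 3.78 CPM in OIR and 5.44 ± 1.32 in nonOIR (SD, n = 8). Camera called the monocyte list up (adjusted p = 0.00173, and 0.0244 with an estimated correlation), though not within lane 2 (adjusted p = 0.141).

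Macrophages of the retinal borders and vessels have their own markers, of which 2 of 13 tested rose (4 adjusted over the list alone), Dab2 from 31.6 ± 15.0 to 86.8 ± 60.8 CPM and Tgfbi. Dab2 lost its call when any of 6 single libraries was left out, and its log2 fold change was 0.35 in lane 1 (edgeR adjusted p = 0.641) and 2.66 in lane 2. Stab1 was at 188 ± 30.3 and 120 ± 54.5 CPM and Ms4a6b at 128 ± 34.3 and 151 ± 47.2 in OIR and nonOIR (SD, n = 8), and neither passed, though Stab1 did with DESeq2, with lane as a covariate (log2 fold change 0.75, edgeR adjusted p = 0.00404) and in lane 2 alone (edgeR adjusted p = 0.000429). This list was called up by camera (adjusted p = 0.00476) but not with an estimated correlation (adjusted p = 0.387) or by its score (exact permutation p = 0.102, adjusted p = 0.281). Its mean log2 fold change was -0.02 in lane 1 and 2.92 in lane 2.

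The list of inner retinal neurons was lower in OIR by its score and by camera at its preset correlation, and the rod list was called by neither. The 2 lists were not shown to differ from each other: the inner-retina minus rod score differed by -0.476 between groups (exact permutation p = 0.467). Of 8 tested genes of bipolar, amacrine and ganglion cells, the neurofilament gene Nefl fell from 5.57 ± 2.16 to 2.28 ± 0.969 CPM (SD, n = 8, also 1 adjusted over the list alone), and the list score was 0.705 ± 0.0946 in OIR and 0.979 ± 0.142 in nonOIR (exact permutation p = 0.000777, adjusted p = 0.00285). Camera called this list down (adjusted p = 0.00703), not with an estimated correlation (adjusted p = 0.111) and not in lane 2 alone (adjusted p = 0.0858). Fry also called it down over all libraries (fry adjusted p = 0.00265). None of 20 rod genes passed, nor did any adjusted over the list alone, with Gnat1, the rod transducin gene, at 38.4 ± 26.96 CPM in OIR and 54.9 ± 30.3 in nonOIR and Gnb1 at 344 ± 49.6 and 275 ± 45.5 (SD, n = 8). Gnb1 passed as higher in OIR with lane as a covariate (log2 fold change 0.32, edgeR adjusted p = 0.00208), in lane 1 alone (edgeR adjusted p = 0.0199) and when OIR replicate 2 or 4 or nonOIR replicate 8 was left out. The rod list did not differ by score (exact permutation p = 0.331, adjusted p = 0.456) or by camera (adjusted p = 0.127). Camera called it down when any of OIR replicates 6, 7 and 8 or nonOIR replicates 2 and 3 was left out, with adjusted p between 0.00824 and 0.0432. It was also called down with scaling by library size only (camera adjusted p = 0.0419) and with voom weights (0.0356). The same held with the border macrophage score (camera adjusted p = 0.00130) or the proliferation score (0.0348) as a covariate.

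In the Müller glia and astrocyte list the intermediate filament gene Vim and the kinetochore gene Spc25 rose 4.83-fold and 3.78-fold and Glul fell to 0.797 (3 rose and 4 fell adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.899). Of 8 tested endothelial genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.577), with Pecam1 at 18.1 ± 9.98 CPM in OIR and 27.8 ± 6.65 in nonOIR (SD, n = 8). Pecam1 passed as lower in OIR with lane as a covariate (log2 fold change -0.75, edgeR adjusted p = 0.0355) and in lane 2 alone (edgeR adjusted p = 0.0251). The lists of cones, pericytes, retinal pigment epithelium and granulocytes or lymphocytes had fewer than 5 tested members. Their scores did not differ (exact permutation p between 0.271 and 0.783). Of their members Acta2 rose, from 0.173 ± 0.147 to 0.744 ± 0.270 CPM (SD, n = 8, a call lost when any of 5 single libraries was left out), and no granulocyte or lymphocyte gene passed the count filter. Of 2 tested pigment epithelium genes 1 fell when adjusted over the list alone. Best1 of that list (log2 fold change -1.12) passed only when nonOIR replicate 1 or 4 was left out, among single omissions.

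Both lanes held OIR and nonOIR libraries, so each could be compared within itself. Adjusted for group, 3104 genes differed between lanes, so the lane code may stand for a wider batch. Lgals3 was higher in OIR in both, from 5.95 ± 1.73 to 53.3 ± 13.9 CPM in lane 1 (SD, n = 5 per group) and from 8.57 ± 4.29 to 297 ± 44.6 in lane 2 (SD, n = 3 per group). Lpl rose in both as well, from 173 ± 21.4 to 404 ± 69.4 CPM and from 78.3 ± 5.92 to 459 ± 25.1. Mmp12 reached 8.38 ± 6.83 CPM in OIR in lane 1, where it did not pass (edgeR adjusted p = 0.127), and 137 ± 19.6 in lane 2 (edgeR adjusted p = 0.00107). Within lane 1, 417 genes changed (276 higher), and within lane 2, 2015 (1260 higher). The lanes shared 317 changed genes, all 317 in the same direction, where independent lists would share 66.6.

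The size of the change differed between lanes for 62 genes (interaction term, edgeR adjusted p under 0.05, with 1632 at unadjusted p under 0.05). Among the 112 named genes these were Lgals3, Lpl, Pkm, Aldoa, Plin2 and C5ar1, which had a larger rise in lane 2, and Nr6a1os, which had a larger fall there. C5ar1 and Nr6a1os did not pass in lane 1 (log2 fold change 0.15 and -0.37, edgeR adjusted p = 0.293 and 0.412). The proliferation list had a mean log2 fold change of 1.91 in lane 1 and 3.47 in lane 2, the glycolysis list 0.13 and 0.81, and the interferon list 1.06 and 1.44. By camera 10 lists differed between lanes, with adjusted p = 3.74e-09 for proliferation, 1.46e-06 for glycolysis and 3.97e-06 for the disease-associated list. With an estimated correlation 0 did (lowest adjusted p = 0.145).

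**Figure D4:**
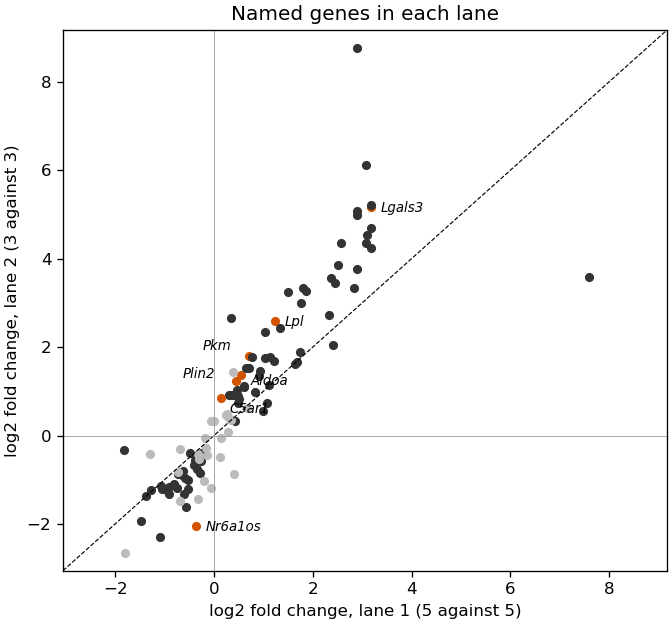
Log2 fold change (OIR over nonOIR) of the named genes within lane 1 (5 against 5 libraries, horizontal axis) and lane 2 (3 against 3, vertical axis), with a dashed line of equal change. Black points changed over all 16 libraries, grey ones did not, and the 7 orange ones differed between lanes.

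The count of changed genes depended on what else the model held: it was 2159 with lane as a covariate, 764 with the border macrophage score, 4 with the proliferation score and 2 with the erythrocyte score. The proliferation score separates the groups (lowest OIR library 3.10, highest nonOIR 2.86, r = 0.873 with group). The erythrocyte score is also closely tied to the group (r = 0.793, variance inflation 2.70). Only 1 OIR library lies at or below its highest nonOIR value (lowest OIR library 0.684, highest nonOIR 1.37). Why so few genes passed with the erythrocyte score was not tested. Camera at its preset correlation called 16 lists with the erythrocyte score, 15 with the border macrophage score and 9 with the proliferation score, against 16 without a covariate. A test against a minimum change of 1.5-fold called 152 genes, 145 of them higher in OIR.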

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

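The tests of globin ratios and correlations and of Ccr2 were chosen after the results were seen. Of 290 groups of 8 values, 11 held a library far from the other 7, where chance gives about 1 in 20 groups, or 14.5. Of these 11, 5 were in OIR replicate 1: Pimreg at 1.07 CPM (next 9.20), Nek2 at 0.0397 CPM (next 2.67), Gla at 8.82 CPM (next 22.6), Slc2a1 at 61.3 CPM (next 87.5) and 16019 genes detected (next 17530). Hbb-bs was at 1.02 CPM in OIR replicate 2 (next 21.5), and Vtn at 0 CPM in OIR replicate 3 (next 1.11). Among nonOIR libraries, Cfb was at 0.130 CPM in replicate 8 (next 0.444), Gnb3 at 0 CPM in replicate 2 (next 1.33), Glul at 241 CPM in replicate 7 (next 277) and the erythrocyte score at 1.37 in replicate 8 (next 0.754).

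Globin transcripts were higher in OIR. Alas2, an erythroid gene chosen after its values were seen, stood at 4.46 ± 5.28 CPM in OIR and 0 in nonOIR (SD, n = 8). Its counts ranged from 0 in OIR replicate 1 to 313 in OIR replicate 8. Over the 8 OIR libraries log2 Hba-a1 and log2 Hbb-bs rose and fell together (r = 0.988, exact permutation p = 7.44e-05, adjusted p = 0.000223 over 3 relations; rho = 0.976, exact p = 0.000397, adjusted p = 0.00119; r = 0.974 without OIR replicates 2 and 8), which is consistent with RNA of erythroid cells in the OIR samples, although a sort for tdTomato, CD11b and low CD45 would be set to leave such cells out. In lane 2 the alpha-globin share of alpha-globin and Hbb-bs counts was 28.2% in OIR (27.4 to 29.1%) and 0.521% in nonOIR (3 of 576 counts, upper bound 1.51%), or 1.87% (2 of 107, upper bound 6.59%) without nonOIR replicate 8. These bounds pool reads and leave out the spread between libraries. By library the share was 21.1, 24.3 and 30.6% in OIR replicates 6, 7 and 8. It was 2.44, 1.52 and 0.213% in nonOIR replicates 6, 7 and 8, with 1 alpha-globin count each. These values argue against more of the source seen in those nonOIR libraries, though on few alpha-globin counts. In lane 1 the pooled share was 28.95% in OIR and 15.6% in nonOIR (7 of 45 counts, 6.49 to 29.5%), with nonOIR replicates 1 (2 of 6 counts) and 4 (3 of 10) at 33.3% and 30%, inside the OIR range of 21.1 to 36.8%, and replicates 2 (2 of 28) and 5 (0 of 1) at 7.14% and 0%, outside it, so more of the source seen there stays open. For Hmox1 and the globin RNA the measures differ and the relation stays open: the lane-centred r was 0.704 (exact within-lane permutation p = 0.113, adjusted p = 0.113), rho 0.857 (exact p = 0.0236, adjusted p = 0.0354) and r 0.741 (exact p = 0.111) without OIR replicates 2 and 5, and OIR replicate 2, with Hbb-bs at 1.02 CPM, had Hmox1 at 261 CPM, above the highest nonOIR value of 82.4.

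Transcripts of inner retinal neurons were lower in OIR, which could reflect less neuronal RNA of every kind carried into the sort. That explanation and a change in inner neurons cannot be told apart: the inner-retina minus rod score differed by -0.476 between groups (exact permutation p = 0.467), with rod scores spread widely. With the rod score as a covariate camera at its preset correlation kept the list's call (adjusted p = 0.0111, mean log2 fold change -0.98), a call that was lost without the covariate once the correlation was estimated (adjusted p = 0.111), and without the covariate 1 of its 8 tested members passed. With the covariate Nefl (log2 -1.29, edgeR adjusted p = 0.0158) and Snap25 (-1.31, edgeR adjusted p = 0.0340) were about as low as without it. The rod score was only weakly tied to the group (r = -0.257, variance inflation 1.07). Adding it could hardly move a change between groups, so these fits do not decide between the 2 explanations. Of the list's 23 genes 7 reached 1 CPM in nonOIR, against 20 of 20 rod genes.

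Disease-associated genes were higher in OIR, and other macrophages or dividing cells might contribute. With the border macrophage score as a covariate 11 of the 13 members that rose still passed, with a median log2 fold change of 1.27 against 1.34. That score was only loosely tied to the group (r = 0.428, variance inflation 1.22). Adding it can take away only part of a change between groups, so this fit does not decide whether border macrophages contribute. With the proliferation score 0 of 13 passed (median 0.68), but that score is strongly tied to the group (r = 0.873), so a share of dividing cells stays open. Monocytes stay open too: Ccr2 did not differ (edgeR adjusted p = 0.935) while the monocyte list rose, the sort removed Ly6C-positive cells, and 4 of that list's 17 genes are in another list. A change within microglia under OIR was not tested apart from these.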

How the results depend on the processing

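The tests with OIR replicate 1 and nonOIR replicate 8 left out, with thinned counts, with erythrocyte, border macrophage and proliferation scores and of named genes with each library left out were chosen after the data were seen. The count of 1368 changed genes became 2159 with lane as a covariate, 417 in lane 1 alone (the cause was not tested), 152 at a minimum fold of 1.5 (a stricter test), 764 with the border score, 2 with the erythrocyte score and 4 with the proliferation score. The proliferation score does not overlap between groups (r = 0.873 with group). For the erythrocyte score only 1 OIR library lies at or below the highest nonOIR value (r = 0.793, variance inflation 2.70). The cause of the low count with the erythrocyte score was not tested. The count of changed genes stayed between 977 and 2021 under the other settings, and between 935 (without OIR replicate 6) and 1556 (without OIR replicate 1) when 1 library was left out. The 16 shifted lists became 9 with the proliferation score and 7 with an estimated correlation, and 15 to 18 with 1 library left out. With the replicate number as a block 1679 genes and 16 lists passed. Same-numbered libraries correlated at -0.0156 to 0.202, 2 of 8 over 0.1, and 2 OIR libraries matched their own number best. Lane was not removed before correlating, and the labels do not say what the numbers mark. These correlations therefore do not show pairing by number and cannot exclude it.

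With the proliferation score, mean log2 changes turned to 0.11 (homeostatic), -0.59 (glycolysis), -0.18 (hypoxia) and -0.0600 (oxidative phosphorylation), and single genes to -1.12 (Mmp12), -1.15 (Nek2), -0.30 (Ccnb2), 0.0837 (Klf12), 0.0116 (Nr6a1os), -0.0550 (Pkm), -0.0385 (Plin2), 0.13 (Ang), -0.0511 (Ccl4), -0.0183 (C5ar1), -0.0665 (Uqcrq), 0.0700 (Glul) and -0.63 (Dab2). Score and group are correlated (variance inflation 4.21), and the cause of these reversals was not tested. Hbb-bt turned to -1.50 with the erythrocyte score, of which it is a member, and the cause was not tested. Over all settings, values of named genes kept direction and call 1766 times, were weaker 285, stronger 41 and reversed 14 times, and those of lists 785, 36, 12 and 4 times. With each library left out, 78 of 87 called named genes kept their call and 0 changed sign. The call was lost without at least 1 library for Hbb-bt (13 libraries), Snap25 (11), 9430060I03Rik (10), Ms4a4c (9), Dab2 (6), Acta2 (5), Klf12 and Calcrl (3 each: OIR replicates 4 and 7 and nonOIR replicate 4, and OIR replicates 6 and 8 and nonOIR replicate 7) and Gpr165 (nonOIR replicate 7). Among called genes the fold moved by more than 1.5 times for Mmp12 (log2 6.00 without nonOIR replicate 7), Cfb (1.73 without OIR replicate 3), Hbb-bs and Hbb-bt (6.44 and 4.93 without nonOIR replicate 8). Among uncalled named genes it did for Hbegf (-2.64 without OIR replicate 5). Of the uncalled genes 4 gained a call without at least 1 library, Hbegf among them.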

Other observations

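Antioxidant genes were higher in OIR, a group noticed in the data; the members named here were chosen after their values were seen. Slc7a11, the cystine transporter gene, rose 6.20-fold, Srxn1 5.58-fold and Gclm 4.02-fold. A shared rise beyond those genes was tested as a hypothesis on 22 further antioxidant genes, listed before their values were examined. Of these 14 rose and 0 fell, with a median log2 fold change of 0.63 (camera p = 0.0123 with an estimated correlation), among them the haem transporter gene Slc48a1 (2.65-fold) and Prdx1 (2.41-fold). The result is consistent with a shared antioxidant response in OIR libraries, without showing which cells carry it.

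Ikbke, a kinase gene chosen after its values were seen, had 406 counts over the OIR and 2 over the nonOIR libraries (2.00 ± 0.933 and 0.0103 ± 0.0191 CPM, SD, n = 8). Apoe differed more by lane than by group: in OIR it stood at 14082 CPM in lane 1 and 1977 in lane 2, and in nonOIR at 8949 and 1316. With lane as a covariate its log2 fold change in OIR was 0.63 (edgeR adjusted p = 0.00139). Of the 16 libraries 3 had under 1 CPM of Xist (X inactivation), 2 under 1 CPM of Ddx3y (Y-linked) and 11 had both genes at or above that level. These were 5 OIR and 6 nonOIR libraries. In them the mean log2(CPM + 1) was at least 2.53 for the Y-linked list (4 genes) and 3.33 for the X-inactivation list (2 genes). In the remaining libraries the list of the missing gene scored at most 0.0899. These values argue against RNA of 1 sex only in those 11 libraries. Whether this reflects pooled animals was not tested, and sex was not a covariate in any model.

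The authors' deposited table called 1977 of 13718 genes, 1120 higher and 857 lower. Of these 1364 were also called here, 613 were in the authors' table only and 4 here only, with 0 differences in sign. The sizes differed: the authors' log2 fold changes had a slope of 0.561 on those found here (r = 0.921 across genes). Mmp12 was at 0.80 in the authors' table against 5.36 here, and Hbb-bs at 0.77 against 4.57. P2ry12 was close, at -0.74 against -0.78. The processing notes name DESeq2 without its role, so whether the authors' fold changes were shrunk is not known. The sizes may therefore be unlike measures, and the cause of the difference was not tested.

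Other splits of the samples were counted. Of 100 splits into 8 and 8, 1 (the real one) gave as many as 1368 genes, the highest other giving 4. A share of 1 in 100 is the smallest that these splits can give. It also treats the 16 libraries as separate samples, which the labels do not state. For lists, 2 of 100 splits gave as many as 16, the highest other giving 16, so the list count alone is weak even though the share lies under 0.05. In lane 1, 1 of 100 gave as many as 417 genes (highest other 1). In lane 2 the real split gave 2015 and the highest other 0, but 10 splits are too few for a share under 0.05. For the 62 genes whose change differed between lanes, 2 of 100 reassignments gave as many. The other gave 2091: it followed lane in nonOIR only, which points to structure in the samples.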
